A study of Escherichia coli with 9 samples.

How the data were processed

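RNA from cultures of E. coli K-12 MG1655 was sequenced in 9 libraries, 3 each with 2% (v/v) methanol, 10 µM toxoflavin or 100 µM tropolone. The labels give 14 h of growth in LB at 37 °C and 2 h with the compound, RNA extraction with RNeasy Midi columns, removal of ribosomal RNA with MICROBExpress, TruSeq libraries and sequencing on a HiSeq2000. The processing notes of the labels name BWA, SAMtools, featureCounts and Subread without a role or a version. Read length, read filtering, strand use and the treatment of reads with more than 1 placement are not given in the sources used here.

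The deposited table of each library gives, per the file headers, raw read counts for 4355 genes with their locus, position on NC_000913.3 and length. The deposited tables also hold RPKM, per the file headers, and recomputing it from the counts, lengths and library totals gave the same values to within 4.98e-06. Counts were used for every test and RPKM only for the test of background reads. Of the 4355 loci 4351 were found in the reference gene table, 4331 of them at the same coordinates, with 4238 protein-coding loci, 113 pseudogenes and 0 ribosomal RNA, transfer RNA or other noncoding loci. Read totals in genes were 9824246, 22074242 and 15633475 for methanol, 2041864, 2076603 and 3088776 for toxoflavin, and 7989740, 7316762 and 3704623 for tropolone.

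Groups were taken from the sample labels. The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from the alternatives named below as added. Counts were filtered with filterByExpr, which kept 4167 genes and left out 188, and scaled with TMM factors of 0.904 to 1.19. All 9 libraries were fitted in 1 quasi-likelihood model (edgeR 4.0.16, robust dispersion, common biological coefficient of variation 0.144), and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. CPM are TMM-scaled means with SD over n = 3. The standard error (SE) given with a log2 fold change is approximate. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. No gene was left out for being ribosomal RNA, because the tables hold none, so the alternative that keeps such genes was not run.

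Gene lists written from textbook knowledge held 739 entries found in the tables and 4 that were not. The 45 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg over the lists. Estimated from the data, this correlation had a median over the lists of 0.148, 0.148 and 0.149 in the 3 comparisons. The genes of some lists, such as ATP synthase, NADH dehydrogenase I and ISC, share an operon, so counts of their members are not counts of independent genes. Members were also counted with the adjustment over the list alone. For each compound against methanol the named genes were the 10 largest rises and 10 largest falls with a mean of at least 10 CPM in 1 of the groups and no overlap between groups, and for the direct comparison the 5 largest in each direction. To these were added, for each of the 45 lists, up to 4 members called by edgeR with the largest changes, and 10 stress genes fixed in advance. Genes named beyond this rule were chosen after their values were seen. In the report these were ahpF, dps, sdhC, gadX, gadW, bolA, iscR, clpB and groL after toxoflavin, bolA, katE, kefC, yoeB and pflB after tropolone, and relB, relE, higA and higB in the direct comparison. In the closing section they were nrdH, nrdI, nrdE, nrdF, puuB, puuE, oppA, dppA, rpoS, hcp, ytfE, ygbA and sdhC. The 5 NsrR targets tested there also stand outside the rule, but were chosen before their values were looked at.

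Precision was tested on simulated data for each comparison, with 200 changed genes. The gene means and dispersions were those of all 9 libraries in each comparison, so the rates do not reflect the gene means of a single group. edgeR recovered 36.9% of 1.5-fold, 90.9% of 2-fold and 95.5% of 4-fold changes for toxoflavin against methanol, and 46.3%, 77.3% and 100% for tropolone against methanol. For toxoflavin against tropolone the shares were 34.3%, 78.8% and 95.4%. False calls made up 3.92%, 5.73% and 3.52% of calls in the 3 simulated comparisons. The simulations changed only 200 genes, by at most 4-fold. In the data edgeR called 3143, 2048 and 2855 genes, so these rates need not hold for the real comparisons.

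The alternatives were a DESeq2 1.42.0 Wald test, limma-voom, median-ratio factors, library totals only, no low-count filter, only the 2 groups compared, a fit without robust dispersion, the replicate number as a block, and leaving out each library in turn. For the lists they were also camera with the correlation estimated from the data, and fry. fry tests whether the members of a list changed at all, and camera whether they changed more than other genes. For the overlap of the responses they included only genes with a mean CPM of at least 10. Thinning every library to the smallest total of 2041864 reads, and library totals only for the lists, were added after the data were seen. The correlation between the responses was compared with 20 simulations of unchanged groups that share their controls. The software was R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library and no column was left out.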

Results

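RNA sequencing measured transcripts of Escherichia coli K-12 MG1655, the wild-type laboratory reference strain, in 9 libraries. Cultures of 3 ml were grown in LB for 14 h at 37 °C with shaking and then kept with a compound or its solvent for 2 h, after which RNA was taken from 1 ml. Of the 9 libraries, 3 came from cultures with 10 µM toxoflavin, a yellow redox-cycling toxin made by Burkholderia pathogens of rice. Another 3 came from cultures with 100 µM tropolone, a metal-chelating aromatic compound with a ketone and a hydroxyl group. The last 3 came from cultures with 2% (v/v) methanol, the solvent of both compounds, and the methanol level of the cultures given a compound is not given in the sources used here. The replicates are not said to be separate cultures, so p-values measure only the spread between these samples.

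Reads counted in genes totalled 9824246, 22074242 and 15633475 in methanol replicates 1 to 3. The toxoflavin libraries held 2041864, 2076603 and 3088776 reads, and the tropolone libraries 7989740, 7316762 and 3704623. Depth therefore differed with the group, and the median gene had 49.0 to 75.0 reads in the toxoflavin libraries, 246 to 536 in the methanol libraries and at least 96.0 in the tropolone libraries. The gene with the most reads was aceB, malate synthase of the glyoxylate shunt, in each methanol library (4.25% to 4.99% of reads) and each tropolone library (6.33% to 6.99%). In each toxoflavin library it was dnaK, the major chaperone of the heat shock response (3.67% to 4.45%). Between tropolone replicate 3 and the other 2 tropolone libraries the chi-square per degree of freedom was 46.2 and 48.3, against 7.91 between those 2. It was as high between methanol replicate 2 and the other methanol libraries, 49.8 and 55.4, against 26.7 between those. In the toxoflavin group it was 7.95 to 8.11. This measure grows with read depth, so it does not rank the groups. Spearman correlations, which low read counts lower, were 0.9802 to 0.9831 in the toxoflavin group and 0.9935 to 0.9956 in the methanol group. For tropolone replicate 3 they were 0.9825 and 0.9815, against 0.9954 between the other tropolone libraries.

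Toxoflavin was compared with methanol to find the genes that 2 h with the toxin changed. Among the named genes ibpB and trxC rose most. trxC (b2582, 2718735 to 2719154), which encodes a thioredoxin of the OxyR regulon, rose 134-fold from 31.5 ± 4.74 to 4224 ± 885 CPM (TMM-scaled read counts, mean ± SD, n = 3), a log2 fold change of 7.06 ± 0.21 (SE; edgeR adjusted p = 4.46e-15). ibpB (b3686, 3866469 to 3866897), which encodes a small heat shock protein, rose from 8.43 ± 0.961 to 1125 ± 307 CPM (log2 7.07 ± 0.23; adjusted p = 1.36e-14). rpsJ (b3321, 3452959 to 3453270), the first gene of the S10 ribosomal protein operon, was lowered most, from 1280.5 ± 52.3 to 11.6 ± 2.31 CPM (log2 -6.78 ± 0.19; adjusted p = 2.14e-15).

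Of 4167 genes tested, edgeR called 3143 (75.4%) changed after toxoflavin at an adjusted p under 0.05, with 1536 higher and 1607 lower. With library totals only the balance turned, with 1858 higher and 1356 lower. At a change of 2-fold or more the count was 2253, with 1074 higher and 1179 lower. In 3283 genes (78.8%) the 3 libraries of 1 group did not overlap the 3 of the other, against 10% by chance. camera called 19 of 45 gene lists, 5 higher and 14 lower, and none of the 19 calls held with an estimated correlation between genes. The count with an estimated correlation was 0, against 7 lists at an unadjusted p under 0.05 and 41 lists by fry.

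The OxyR regulon, which answers hydrogen peroxide, rose after toxoflavin. Of its 11 genes tested, 8 rose, 2 fell and 1 was not called, and 8 rose and 2 fell adjusted over the list alone (median log2 fold change 2.94; camera adjusted p = 1.57e-06, and adjusted p = 0.296 with an estimated correlation). grxA (b0849, 890496 to 890753), which encodes a glutaredoxin, rose from 2.66 ± 0.376 to 287 ± 62.3 CPM (log2 6.77), and mntH (b2392, 2511468 to 2512706), the manganese importer, from 120.0 ± 11.1 to 11673 ± 2066 CPM (log2 6.60). hemH, ferrochelatase, changed by a log2 of 5.55 and katG, a catalase-peroxidase, by 3.99. ahpC, an alkyl hydroperoxide reductase subunit, rose by 0.47, whereas its partner ahpF fell (log2 -1.03), and dps, a DNA-binding iron protein, stood at a log2 of 0.18 (adjusted p = 0.212). ypeC, the gene next to mntH, rose from 39.5 ± 1.66 to 1920.0 ± 257 CPM.

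Genes of the SoxRS regulon, which answers superoxide and redox-cycling drugs, went both ways after toxoflavin. Of 17 tested, 7 rose, 8 fell and 2 were not called, with 7 and 8 adjusted over the list alone. The median log2 fold change was 0.17 while the mean was -0.41 (camera adjusted p = 0.722). The regulator soxS rose by a log2 of 1.19 ± 0.32 (adjusted p = 0.00291) and fumC, an iron-free fumarase, by 2.10, whereas nfo, an endonuclease, and zwf, glucose-6-phosphate dehydrogenase, fell (log2 -2.90 and -2.79). The log2 fold change of sodA, manganese superoxide dismutase, was 0.49 ± 0.23 (adjusted p = 0.0711), and 5 of 15 alternatives called it, with adjusted p from 0.00163 to 0.36.

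The SUF and ISC systems both build iron-sulfur clusters, and they moved in opposite directions after toxoflavin. All 6 SUF genes rose, also adjusted over the list alone (median log2 2.80; camera adjusted p = 2.71e-06, and adjusted p = 0.296 with an estimated correlation). sufA (b1684, 1764018 to 1764386) went from 461 ± 46.7 to 6874 ± 442 CPM. Of the 8 ISC genes 7 fell and iscR was not called, with 7 adjusted over the list alone (median -2.31; camera adjusted p = 0.0188, and adjusted p = 0.588 with an estimated correlation). hscB, a co-chaperone gene of that system, had a log2 fold change of -3.25. Of 15 genes for the siderophore enterobactin, 10 rose, 1 fell and 4 were not called, with 10 and 1 adjusted over the list alone (median 0.89; camera adjusted p = 0.041, and adjusted p = 0.588 with an estimated correlation). That call ended without methanol replicate 2 (adjusted p = 0.0654) or without toxoflavin replicate 1 (adjusted p = 0.051), over a range of 0.0223 to 0.0654 in 10 alternatives. fes, the enterobactin esterase, rose by a log2 of 3.18 and the receptor gene fepA by 0.77. Of 26 other Fur-regulated iron uptake genes 7 rose, 14 fell and 5 were not called, with 7 and 14 adjusted over the list alone (median -0.655; camera adjusted p = 0.535). Among those that fell were feoA and feoB, for ferrous iron uptake (log2 -5.22 and -4.95).

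Heat shock genes split after toxoflavin, with 10 of 18 higher and 8 lower, and 10 and 8 adjusted over the list alone (median log2 0.49; camera adjusted p = 0.535). The small heat shock gene ibpA rose by a log2 of 5.66 and hspQ by 3.27. The aggregate-clearing chaperone gene clpB went from 2981 ± 173 to 25857 ± 3798 CPM. The chaperonin gene groL fell from 3396 ± 166 to 429.9 ± 56.2 CPM and hslU, a protease ATPase gene, had a log2 fold change of -3.19. The Cpx envelope stress list had 3 genes higher, 7 lower and 2 not called of 12, and 3 and 7 adjusted over the list alone (median -0.53; camera adjusted p = 0.943). Its periplasmic regulator cpxP stood at 159.7 ± 17.2 CPM in methanol and 2430.1 ± 360.4 after toxoflavin (log2 3.93). Of the 14 genes of the MarA and AcrAB-TolC list, 7 rose, 5 fell and 2 were not called, with 7 and 5 adjusted over the list alone (median 0.35, mean -0.08; camera adjusted p = 0.943). The efflux pump genes acrA and tolC fell (log2 -2.04 and -2.98), and marA stood at 0.32 (adjusted p = 0.199). Library totals only put marA at 0.63, where edgeR called it (adjusted p = 0.0181; range 0.0181 to 0.549 over 15 alternatives). Of the 23 SOS genes 9 rose, 11 fell and 3 were not called, with 9 and 11 adjusted over the list alone (median -0.14; camera adjusted p = 0.641), and recA stood at a log2 of -0.14 (adjusted p = 0.374), or 0.17 with library totals only.

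Toxin-antitoxin genes rose after toxoflavin in 18 of 20, with none lower and 18 adjusted over the list alone (median log2 1.74; camera adjusted p = 1.96e-06, and adjusted p = 0.296 with an estimated correlation). hipA (b1507, 1590854 to 1592176) went from 67.3 ± 6.87 to 1326 ± 219.5 CPM and relB rose by a log2 of 2.88. Flagella and chemotaxis genes rose in 25 of 44, with none lower and 25 adjusted over the list alone (median 0.92; camera adjusted p = 0.0291, and adjusted p = 0.58 with an estimated correlation), and scaling by library totals only ended the call (adjusted p = 0.0673; range 0.00846 to 0.0673). These genes had few reads, with a median of 3.48 RPKM in methanol and 9.18 after toxoflavin, and the 5th percentile of RPKM over all genes was 1.97 to 3.95 in the toxoflavin libraries against 0.866 to 1.90 in the methanol libraries. fliC, which encodes flagellin, rose from 35.0 ± 2.91 to 181 ± 25.5 CPM. Among single genes with large rises were phoH (log2 6.87), an ATPase gene of the phosphate regulon, hmp (log2 6.22), a nitric oxide dioxygenase, bhsA (log2 6.19) and azuC (log2 5.76, from 115 reads in the 3 toxoflavin libraries).

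**Figure D1:**
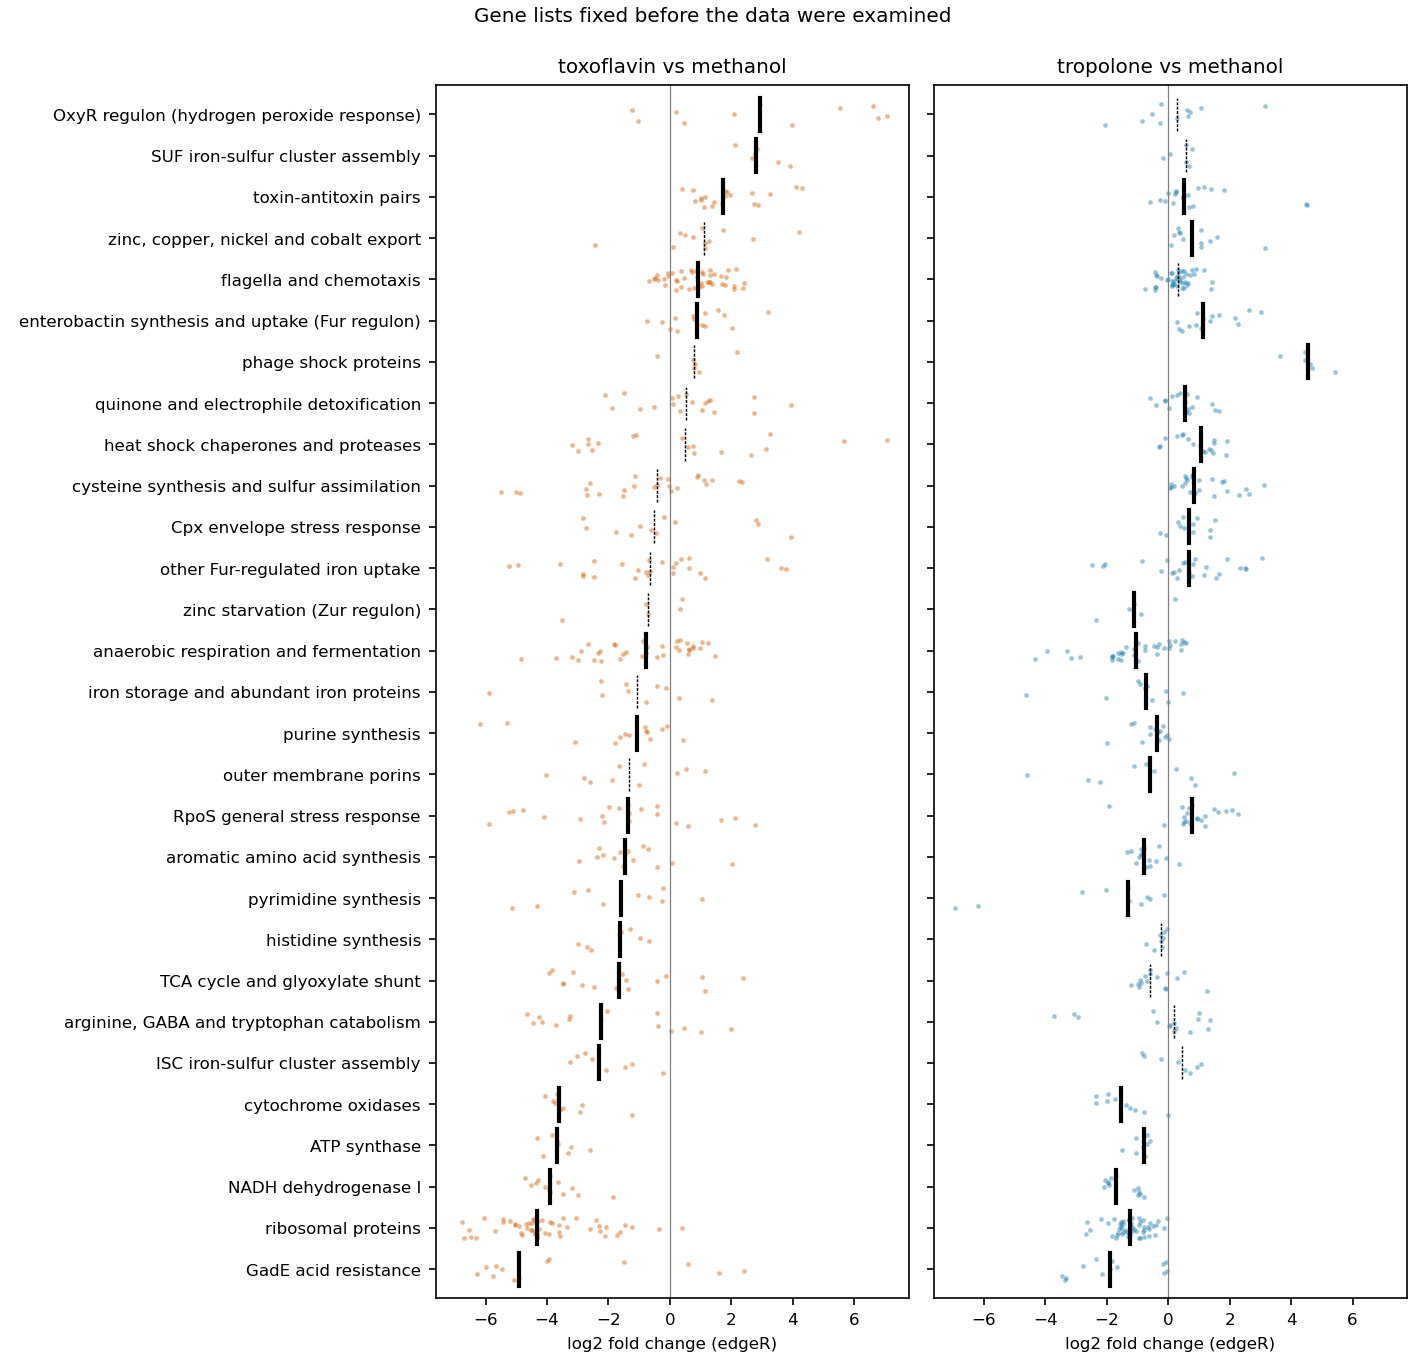
Log2 fold change of each tested member (points) of the 29 gene lists that camera called in at least 1 of the comparisons with methanol, for toxoflavin and for tropolone, with a thick bar at the median of a called list and a thin dashed bar at the median of a list that was not called. Ribosomal protein genes have a median of -4.33 after toxoflavin and -1.24 after tropolone, and phage shock genes one of 4.54 after tropolone.

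Ribosomal protein genes fell after toxoflavin in 53 of 54, with none higher and 53 adjusted over the list alone (median log2 -4.33; camera adjusted p = 2.6e-28, and adjusted p = 0.296 with an estimated correlation). rplC, rplW, rplD and rplB, which follow rpsJ in the S10 operon, had log2 fold changes of -6.69, -6.54, -6.49 and -6.32. Respiratory genes fell too. All 13 genes of NADH dehydrogenase I were lower, also adjusted over the list alone (median -3.91; camera adjusted p = 4.13e-13, and adjusted p = 0.281 with an estimated correlation). Lower as well were all 8 of ATP synthase (median -3.66; camera adjusted p = 2.97e-07, and adjusted p = 0.296 with an estimated correlation) and all 10 of the cytochrome oxidases (median -3.60; camera adjusted p = 1.4e-06, and adjusted p = 0.338 with an estimated correlation). These counts were likewise 8 and 10 adjusted over the list alone. nuoM went from 993 ± 62.3 to 38.1 ± 4.71 CPM and atpA from 2489.6 ± 279 to 142 ± 11.4 CPM. Of the 16 genes of the TCA cycle and glyoxylate shunt, 3 rose, 12 fell and 1 was not called, with 3 and 12 adjusted over the list alone (median -1.66; camera adjusted p = 0.00679, and adjusted p = 0.588 with an estimated correlation). aceA, isocitrate lyase, went from 30687 ± 1757 to 2022 ± 311 CPM, whereas sdhC, a succinate dehydrogenase subunit gene, rose by a log2 of 2.39.

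Acid resistance genes controlled by GadE fell after toxoflavin in 10 of 13 and rose in 3, with 10 and 3 adjusted over the list alone (median log2 -4.90; camera adjusted p = 2.63e-08, and adjusted p = 0.239 with an estimated correlation). gadE (b3512, 3658366 to 3658893), the regulator itself, went from 1389 ± 56.3 to 17.8 ± 5.60 CPM and the periplasmic chaperone gene hdeB from 1683 ± 183 to 26.5 ± 7.09 CPM, while the regulators gadX and gadW rose (log2 2.41 and 1.60). RpoS general stress genes fell in 16 of 21, rose in 4 and were not called in 1, with 16 and 4 adjusted over the list alone (median -1.37; camera adjusted p = 0.00184, and adjusted p = 0.58 with an estimated correlation). katE (b1732, 1813867 to 1816128), a catalase, went from 5384 ± 385 to 92.0 ± 8.09 CPM, and yciE and yciF had log2 fold changes of -5.24 and -5.11, whereas bolA, a morphology gene, rose by 2.78. Of 36 anaerobic respiration and fermentation genes 16 fell, 5 rose and 15 were not called, with 16 and 5 adjusted over the list alone (median -0.76; camera adjusted p = 0.041, and adjusted p = 0.438 with an estimated correlation). That call ended without methanol replicate 2 (adjusted p = 0.0662), without toxoflavin replicate 1 (0.051) and without toxoflavin replicate 2 (0.0508), over a range of 0.014 to 0.0662.

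Biosynthesis genes were lower after toxoflavin in several lists. All 8 histidine genes fell, also adjusted over the list alone (median log2 -1.62; camera adjusted p = 0.00889, and adjusted p = 0.296 with an estimated correlation). Of 14 purine genes 11 fell and 1 rose, with 11 and 1 adjusted over the list alone (median -1.07; camera adjusted p = 0.00889, and adjusted p = 0.438 with an estimated correlation). guaA, GMP synthase, went from 1209.7 ± 135 to 16.7 ± 4.31 CPM. Of 10 pyrimidine genes 7 fell, also adjusted over the list alone (median -1.60; camera adjusted p = 0.0291, and adjusted p = 0.438 with an estimated correlation), with pyrB, the catalytic subunit of aspartate transcarbamoylase, at a log2 of -5.13. Of 15 aromatic amino acid genes 13 fell and 1 rose, with 13 and 1 adjusted over the list alone (median -1.47; camera adjusted p = 0.0156, and adjusted p = 0.497 with an estimated correlation). Of 15 genes for the breakdown of arginine, GABA and tryptophan 11 fell and 3 rose, with 11 and 3 adjusted over the list alone (median -2.25; camera adjusted p = 0.00373, and adjusted p = 0.296 with an estimated correlation). tnaA, tryptophanase, had a log2 fold change of -4.28 against 1.98 for astC of arginine breakdown. The peptide permease gene oppB went from 1155 ± 177 to 17.0 ± 2.18 CPM. Scaling by library totals only moved the median log2 fold change of all genes from 0.05 to 0.35, so a change after toxoflavin smaller than this shift depends on the scaling.

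Tropolone was compared with methanol to find the genes that 2 h with the chelator changed. All 6 phage shock genes, which answer damage to the inner membrane, rose, with the highest median of the 45 lists, a camera call lost with an estimated correlation (adjusted p = 0.169). hmp, the nitric oxide dioxygenase gene, rose most among the named genes, from 28.6 ± 4.25 to 2805 ± 308 CPM (n = 3; log2 6.62 ± 0.17; edgeR adjusted p = 1.06e-14; b2552, 2685835 to 2687025). pspA (b1304, 1368079 to 1368747), the effector of the phage shock response, rose 43.3-fold from 79.4 ± 7.72 to 3440.4 ± 862 CPM (log2 5.44 ± 0.20; adjusted p = 1.71e-13). pyrB (b4245, 4471460 to 4472395), the catalytic subunit gene of aspartate transcarbamoylase, went from 455 ± 98.1 to 3.80 ± 0.508 CPM (log2 -6.93 ± 0.22; adjusted p = 7.26e-14), and hyaB (b0973, 1033254 to 1035047), the large subunit gene of hydrogenase 1, from 1329 ± 59.4 to 35.6 ± 3.30 CPM (log2 -5.21 ± 0.17; adjusted p = 8.02e-14).

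Of the 4167 genes, edgeR called 2048 (49.1%) changed after tropolone, with 1017 higher and 1031 lower. Library totals only gave 1050 higher and 979 lower. At 2-fold or more the count was 812, with 395 higher and 417 lower. In 2418 genes (58.0%) the groups did not overlap, against 10% by chance. camera called 22 of the 45 lists, 10 higher and 12 lower. With an estimated correlation the count was 0, against 8 lists at an unadjusted p under 0.05 and 34 lists by fry. Without tropolone replicate 3 edgeR called 2088 genes, 1899 of them among the 2048, and camera called 21 lists.

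All 6 phage shock genes rose after tropolone, also adjusted over the list alone (median log2 4.54; camera adjusted p = 2.51e-17, and adjusted p = 0.169 with an estimated correlation). The estimated correlation between these genes was 0.897, against the preset 0.01, so their rises are not independent. pspB, pspC, pspG and pspD had log2 fold changes of 4.67, 4.62, 4.45 and 4.44. After toxoflavin 5 of the 6 rose, also adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.315). Cpx genes rose after tropolone in 8 of 12 with none lower, and 9 rose and 1 fell adjusted over the list alone (median 0.67; camera adjusted p = 0.0238, and adjusted p = 0.263 with an estimated correlation), among them cpxP (log2 1.37) and spy (log2 1.37), a periplasmic chaperone gene. Heat shock genes rose in 14 of 18 with none lower, and 15 rose and 1 fell adjusted over the list alone (median 1.07; camera adjusted p = 0.000115, and adjusted p = 0.302 with an estimated correlation). dnaK went from 5750.0 ± 639 to 21046 ± 1813 CPM and ibpA rose by a log2 of 1.91. RpoS genes rose in 19 of 21, with aidB lower and bolA not called, and 19 rose and 1 fell adjusted over the list alone (median 0.78; camera adjusted p = 3.64e-05, and adjusted p = 0.345 with an estimated correlation). The trehalase gene treA had a log2 fold change of 2.28 and yciG of 2.07.

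Iron uptake genes rose after tropolone. Of the 15 enterobactin genes 11 rose and none fell, with 12 higher adjusted over the list alone (median log2 1.12; camera adjusted p = 4.33e-07, and adjusted p = 0.263 with an estimated correlation). fes went from 49.0 ± 6.07 to 399 ± 72.9 CPM and fepA from 55.0 ± 15.1 to 119.5 ± 10.1 CPM. Of 26 other Fur-regulated genes 16 rose, 4 fell and 6 were not called, with 16 and 4 adjusted over the list alone (median 0.67; camera adjusted p = 0.0031, and adjusted p = 0.424 with an estimated correlation). yncE and the citrate uptake regulator fecI had log2 fold changes of 3.05 and 2.53, whereas feoB fell (log2 -2.47). Genes of iron storage and abundant iron proteins fell in 6 of 10, with katE higher and 3 not called, and 6 fell and 1 rose adjusted over the list alone (median -0.73; camera adjusted p = 0.00265, and adjusted p = 0.263 with an estimated correlation). sodB (b1656, 1735378 to 1735959), iron superoxide dismutase, went from 2549.6 ± 145 to 102 ± 16.0 CPM, and bfr, bacterioferritin, from 407 ± 72.4 to 99.3 ± 9.46 CPM. After toxoflavin 7 of these 10 genes fell and 2 rose (median -1.06; camera adjusted p = 0.0624). Between the compounds 4 were higher and 5 lower after toxoflavin, and the list was not called (median -0.11; camera adjusted p = 0.987).

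Zinc, copper, nickel and cobalt export genes rose after tropolone in 7 of 12 with none lower, also adjusted over the list alone (median log2 0.78; camera adjusted p = 0.0186, and adjusted p = 0.388 with an estimated correlation). zntA (b3469, 3606451 to 3608649), the zinc exporter, went from 373 ± 27.0 to 3301 ± 425 CPM. After toxoflavin 8 of the 12 export genes rose and 1 fell (median 1.10; camera adjusted p = 0.138). Between the compounds 3 were higher and 3 lower after toxoflavin, and the list was not called (median 0.01; camera adjusted p = 0.891). Zinc uptake genes of the Zur regulon fell after tropolone in 4 of 5, also adjusted over the list alone (median -1.10; camera adjusted p = 0.0467, and adjusted p = 0.346 with an estimated correlation). znuA, the periplasmic zinc-binding protein gene, had a log2 fold change of -2.34. The Zur call ended without tropolone replicate 2 (adjusted p = 0.0526), without tropolone replicate 3 (0.0815), with library totals only (0.0512) and with libraries thinned to the smallest total (0.107), over a range of 0.0199 to 0.107. Of 25 genes for cysteine synthesis and sulfur assimilation 15 rose and none fell, with 16 higher adjusted over the list alone (median 0.85; camera adjusted p = 3.64e-05, and adjusted p = 0.287 with an estimated correlation). sbp, the sulfate-binding protein gene, went from 10.5 ± 1.16 to 91.3 ± 16.8 CPM and cysD from 652 ± 217 to 3998 ± 419 CPM. Quinone and electrophile detoxification genes rose in 12 of 19, with kefC lower, and 12 rose and 2 fell adjusted over the list alone (median 0.53; camera adjusted p = 0.0315, and adjusted p = 0.352 with an estimated correlation), with gloA, glyoxalase I, at a log2 of 1.66. Toxin-antitoxin genes rose in 10 of 20 with yoeB lower, and 11 rose and 1 fell adjusted over the list alone (median 0.50; camera adjusted p = 0.000308, and adjusted p = 0.387 with an estimated correlation). relB and relE had log2 fold changes of 4.51 and 4.49, as hokD of the same operon had 4.93. puuA, for putrescine breakdown, went from 26.4 ± 3.66 to 849 ± 39.8 CPM.

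**Figure D2:**
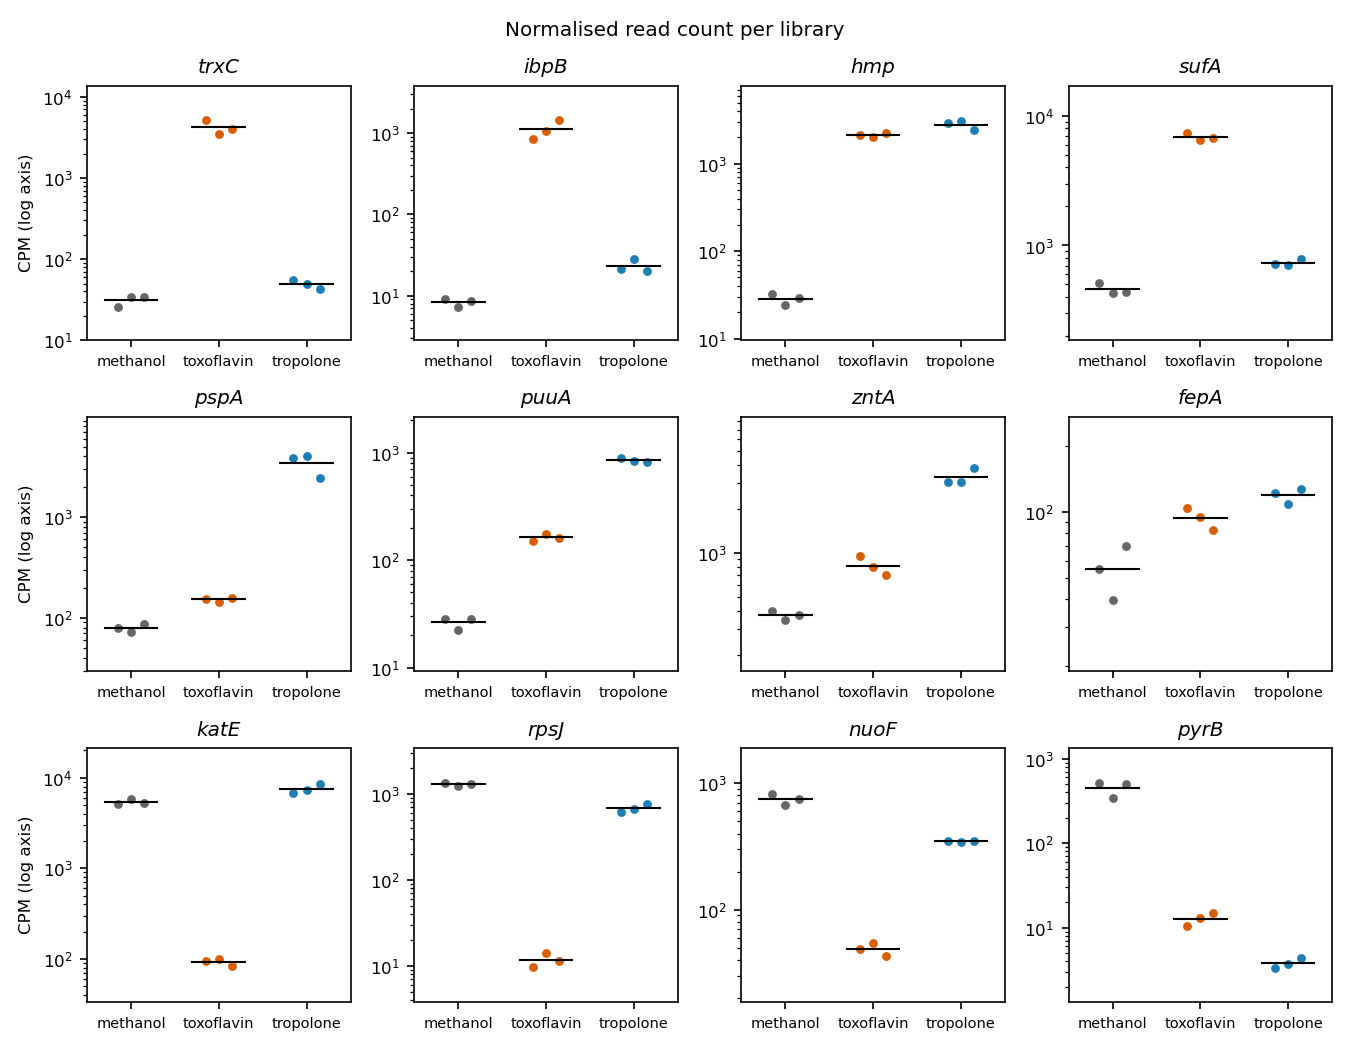
CPM of 12 genes, chosen after their values were seen, on a log axis, 1 point per library and a bar at the mean of each group (n = 3), for methanol, toxoflavin and tropolone. hmp is higher after both compounds, trxC and ibpB reach 4224 and 1125 CPM after toxoflavin, and pspA and puuA are highest after tropolone.

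Ribosomal protein genes fell after tropolone in 51 of 54, also adjusted over the list alone (median log2 -1.24; camera adjusted p = 3.74e-13, and adjusted p = 0.316 with an estimated correlation). The list median was -1.14, -0.997 and -1.74 in tropolone replicates 1, 2 and 3, and -1.09 without replicate 3. Lower as well were all 13 genes of NADH dehydrogenase I (median -1.70; camera adjusted p = 1.76e-09, and adjusted p = 0.203 with an estimated correlation). So were 9 of 10 for cytochrome oxidases (median -1.54; camera adjusted p = 5.72e-06, and adjusted p = 0.316 with an estimated correlation) and all 8 of ATP synthase (median -0.78; camera adjusted p = 0.0131, and adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone these counts were 13, 9 and 8. rplM and cydA had log2 fold changes of -2.69 and -2.35. Of 36 anaerobic genes 20 fell and pflB rose, with 21 lower and 2 higher adjusted over the list alone (median -1.05; camera adjusted p = 4.55e-07, and adjusted p = 0.169 with an estimated correlation). narG, of nitrate reductase A, went from 817 ± 16.0 to 40.9 ± 3.96 CPM. GadE acid resistance genes fell in 9 of 13 with none higher, also adjusted over the list alone (median -1.91; camera adjusted p = 6.97e-12, and adjusted p = 0.159 with an estimated correlation), with gadC, the glutamate antiporter gene, at -3.46.

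Pyrimidine genes fell after tropolone in 8 of 10 with none higher, also adjusted over the list alone (median log2 -1.30; camera adjusted p = 7.31e-07, and adjusted p = 0.169 with an estimated correlation). pyrI and carA had log2 fold changes of -6.18 and -2.82. Of 15 aromatic amino acid genes 12 fell and none rose, with 13 lower and 1 higher adjusted over the list alone (median -0.80; camera adjusted p = 0.00693, and adjusted p = 0.392 with an estimated correlation). Of 14 purine genes 6 fell and none rose, also adjusted over the list alone (median -0.38; camera adjusted p = 0.0427, and adjusted p = 0.424 with an estimated correlation). This call ended without tropolone replicate 2 (adjusted p = 0.0533; range 0.0321 to 0.0533). Of 10 outer membrane porin genes 6 fell and 3 rose, with 6 and 3 adjusted over the list alone (median -0.59; camera adjusted p = 0.0452, and adjusted p = 0.263 with an estimated correlation). ompW and ompF fell (log2 -4.61 and -2.61) and ompX rose by 2.15. The porin call ended without tropolone replicate 1 (adjusted p = 0.0513), without tropolone replicate 2 (0.0721) and with library totals only (0.0509), over a range of 0.0253 to 0.0721. grcA, a glycyl radical cofactor gene, went from 334 ± 15.6 to 11.4 ± 0.611 CPM, and hybO of hydrogenase 2 from 107 ± 17.0 to 4.16 ± 0.874 CPM.

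Oxidative stress lists were not called after tropolone. Of 11 OxyR genes 5 rose, 3 fell and 3 were not called, with 5 and 4 adjusted over the list alone (median log2 0.28; camera adjusted p = 0.545), and mntH rose (log2 3.14) while katG fell (log2 -2.06). Of 17 SoxRS genes 5 rose, 4 fell and 8 were not called, with 5 and 4 adjusted over the list alone (median -0.12, mean 0.02; camera adjusted p = 0.884). sodA rose by a log2 of 1.24 ± 0.24 (adjusted p = 0.000517), and soxS by 0.76 ± 0.30 (adjusted p = 0.0429), a call that 8 of 15 alternatives ended, with adjusted p from 0.00682 to 0.211. The soxS call ended without methanol replicate 2 (0.169) or 3 (0.211) and without tropolone replicate 1 (0.135) or 2 (0.0659). Of 6 SUF genes 4 rose, also adjusted over the list alone (median 0.59; camera adjusted p = 0.240), and of 8 ISC genes 4 rose and 2 fell, with 4 and 2 adjusted over the list alone (median 0.44; camera adjusted p = 0.601). Of the 14 MarA and AcrAB-TolC genes 2 rose and 2 fell, with 2 and 2 adjusted over the list alone (median -0.00, mean 0.09; camera adjusted p = 0.738), with acrA at a log2 of 0.76, tolC at -0.21 (adjusted p = 0.211) and marA at -0.17 (adjusted p = 0.537). Without tropolone replicate 3 edgeR called tolC lower (log2 -0.31; adjusted p = 0.0486, range 0.0486 to 0.517). The 23 SOS genes had 3 higher, 9 lower and 11 not called, with 4 and 10 adjusted over the list alone (median -0.30; camera adjusted p = 0.240), and recA fell (log2 -0.83; adjusted p = 8.25e-05).

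Toxoflavin was then compared with tropolone directly, at the single dose of each, 10 µM and 100 µM, so the doses were not matched. After toxoflavin 8 of 11 OxyR genes were higher and 2 lower. After tropolone 17 of 21 RpoS genes were higher and 4 lower, and all 6 phage shock genes and 50 of 54 ribosomal protein genes were higher. None of these list calls by camera held with an estimated correlation (adjusted p = 0.333, and 0.383 for phage shock). katG (b3942, 4133835 to 4136015) stood at 31236 ± 4734 CPM after toxoflavin and 472 ± 53.3 after tropolone (n = 3), a log2 difference of 6.05 ± 0.16 (edgeR adjusted p = 4.73e-15), with yijE, the gene beside it, at 5.81. katE stood at 92.0 ± 8.09 and 7512 ± 854 CPM (log2 -6.35 ± 0.16; adjusted p = 4.27e-15), and yciF (b1258, 1315270 to 1315770) at 8.35 ± 2.23 and 1105 ± 145 CPM (log2 -7.00 ± 0.21; adjusted p = 1.26e-14). puuC, an aldehyde dehydrogenase gene of putrescine breakdown, stood at 14.3 ± 2.91 and 1256 ± 108 CPM (log2 -6.48).

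Of the 4167 genes, edgeR called 2855 (68.5%) different between the compounds, with 1344 higher and 1511 lower after toxoflavin, or 1651 and 1269 with library totals only. At 2-fold or more the count was 1979, with 890 higher and 1089 lower. In 2933 genes (70.4%) the groups did not overlap, against 10% by chance. camera called 17 of 45 lists, 3 higher and 14 lower after toxoflavin. With an estimated correlation the count was 0, against 4 lists at an unadjusted p under 0.05 and 36 lists by fry.

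Higher after toxoflavin than after tropolone were OxyR genes, with 8 of 11 higher and 2 lower, also 8 and 2 adjusted over the list alone (median log2 difference 3.17; camera adjusted p = 2.48e-07, and adjusted p = 0.333 with an estimated correlation). trxC and grxA differed by a log2 of 6.42 and 6.48. All 6 SUF genes were higher, also adjusted over the list alone (median 2.77; camera adjusted p = 3.73e-06, and adjusted p = 0.333 with an estimated correlation). Toxin-antitoxin genes were higher in 15 of 20 and lower in 4, with 15 and 4 adjusted over the list alone (median 1.29; camera adjusted p = 0.00421, and adjusted p = 0.541 with an estimated correlation). hipA differed by 3.31, and the 4 lower genes were relB, relE, higA and higB.

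Lower after toxoflavin than after tropolone were RpoS genes, 17 of 21 lower and 4 higher, also 17 and 4 adjusted over the list alone (median log2 difference -2.40; camera adjusted p = 9.57e-09, and adjusted p = 0.333 with an estimated correlation). all 6 phage shock genes, also adjusted over the list alone (median -3.85; camera adjusted p = 1.37e-05, and adjusted p = 0.383 with an estimated correlation). pspA differed by -4.50. Ribosomal protein genes were lower in 50 of 54, also adjusted over the list alone (median -2.84; camera adjusted p = 1.45e-18, and adjusted p = 0.333 with an estimated correlation). Lower too were all 13 genes of NADH dehydrogenase I (median -2.26; camera adjusted p = 4.4e-07) and all 8 of ATP synthase (median -3.03; camera adjusted p = 5.25e-06), both with an adjusted p = 0.333 with an estimated correlation, and all 10 cytochrome oxidase genes (median -1.75; camera adjusted p = 0.00311, and adjusted p = 0.601 with an estimated correlation), with 13, 8 and 10 adjusted over the list alone. GadE genes were lower in 10 of 13 and higher in 3, also adjusted over the list alone (median -1.74; camera adjusted p = 0.00275, and adjusted p = 0.333 with an estimated correlation). gadE differed by -4.14.

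Metabolic lists lower after toxoflavin than after tropolone included cysteine synthesis and sulfur assimilation, with 16 of 25 lower and 4 higher, also adjusted over the list alone (median log2 difference -1.61; camera adjusted p = 0.00144, and adjusted p = 0.484 with an estimated correlation). cysJ, a sulfite reductase subunit gene, stood at 43.7 ± 9.70 and 2273 ± 169 CPM. All 8 ISC genes were lower (median -2.31; camera adjusted p = 0.00194, and adjusted p = 0.541 with an estimated correlation), as were 11 of 13 glycolysis genes (median -1.17; camera adjusted p = 0.00194, and adjusted p = 0.541 with an estimated correlation), with 8 and 11 adjusted over the list alone. Of 26 other Fur-regulated genes 19 were lower and 3 higher, also adjusted over the list alone (median -1.41; camera adjusted p = 0.00925, and adjusted p = 0.684 with an estimated correlation), with fhuF, of ferrioxamine use, at -4.50. Of 15 genes for arginine, GABA and tryptophan breakdown 10 were lower and 1 higher, with 10 and 2 adjusted over the list alone (median -1.43; camera adjusted p = 0.00191, and adjusted p = 0.333 with an estimated correlation). All 8 histidine genes were lower, also adjusted over the list alone (median -1.42; camera adjusted p = 0.0147, and adjusted p = 0.333 with an estimated correlation), a call that ended with libraries thinned to the smallest total (adjusted p = 0.0559; range 0.00989 to 0.0559). Of 16 genes of the TCA cycle and glyoxylate shunt 11 were lower and 3 higher, also adjusted over the list alone (median -1.39; camera adjusted p = 0.0177, and adjusted p = 0.724 with an estimated correlation), a call that ended without toxoflavin replicate 2 (adjusted p = 0.0514; range 0.004 to 0.0514). The 15 enterobactin genes had 1 higher, 5 lower and 9 not called, with 1 and 5 adjusted over the list alone (median -0.34; camera adjusted p = 0.665), and fepA differed by -0.35 ± 0.18 (adjusted p = 0.0892). soxS differed by 0.43 ± 0.33 (adjusted p = 0.252), and edgeR called neither difference. Library totals only moved the median of all genes from 0.03 to 0.30 here.

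Across the 4167 genes, the log2 fold changes of toxoflavin and of tropolone against methanol had a Pearson correlation of 0.487 and a Spearman correlation of 0.469. The correlation is across genes, which are not independent replicates, and both comparisons share the 3 methanol libraries. In 20 simulations of unchanged groups against the same controls, in which 3976 genes on average passed the filter, the Pearson correlation averaged 0.373 (SD 0.0226, highest 0.408) and the Spearman correlation 0.380. The covariance was 0.848 against a simulated 0.0217, a difference of 0.826. The 2 fold changes had the same sign in 66.8% of genes, against 63.9% in the simulations. Both compounds raised 575 genes, against 375 for independent lists, and both lowered 754, against 398. Toxoflavin raised and tropolone lowered 127 genes, against 380.0 for independent lists, and 263 fell after toxoflavin and rose after tropolone, against 392. The 3 controls were not split between the comparisons, because a split leaves 1 comparison with a single control. The simulated covariance, at most 0.0240, argues against noise in the shared controls as the source of most of the covariance. In the simulations at most 1 gene was called higher in both comparisons and 0 lower in both. They held no changed genes, so part of the excess over independent lists may still come from the shared controls. A deviation common to all 3 methanol libraries was not simulated.

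**Figure D3:**
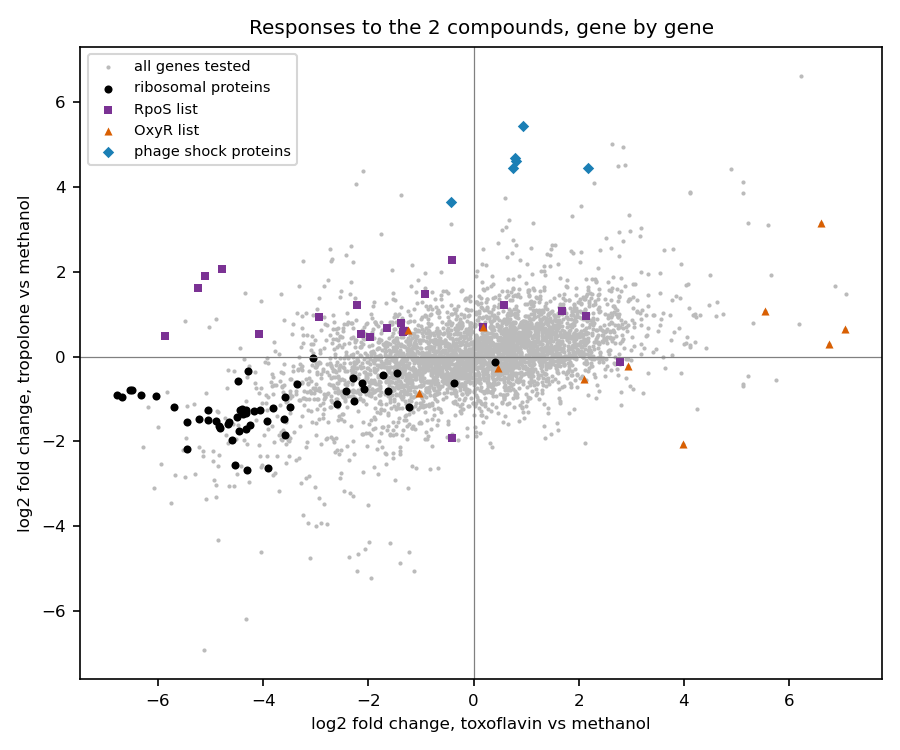
Log2 fold change against methanol after toxoflavin (x axis) and after tropolone (y axis) for all 4167 genes (grey), with ribosomal protein genes as black circles, RpoS genes as purple squares, OxyR genes as orange triangles and phage shock genes as blue diamonds. The Pearson correlation over all genes was 0.487, and the RpoS genes had a median of -1.37 on the x axis and 0.78 on the y axis.

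Some of the genes tested share reads or sequence with others, including pairs not named above. gadA and gadB, and tufA and tufB, are nearly identical pairs whose reads the counting could split, so their separate values are uncertain. The strand setting of the counting is not given in the sources used here, so reads from a gene and from an overlapping antisense transcript cannot be separated.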

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

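For the patterns below, the tests of normalization, those with libraries thinned to the smallest total and the use of library totals only for gene lists were chosen after the results were seen, as was a condition on the background test given with it.

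RpoS general stress genes had opposite directions after the compounds, with a median log2 fold change of -1.37 after toxoflavin and 0.78 after tropolone. The direct difference was -2.40 (camera adjusted p = 9.57e-09, adjusted p = 0.333 with an estimated correlation and 4.72e-06 by fry). Of 3 scalings, library totals only moved the median of all genes after toxoflavin from 0.05 to 0.35, and the list medians, not centred on all genes, stayed on their sides of 0, by at least 0.76 (tropolone, median-ratio factors; SD over libraries 0.123), which argues against the choice among these scalings as the cause. Library depth is argued against by a gap of 2.04 after thinning. Total RNA per cell, different doses, a different effect on growth and different use of RpoS stay open as untested explanations.

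Ribosomal protein genes had a median log2 fold change of -4.33 after toxoflavin. Gene length and mean abundance over all 9 libraries are argued against by 10000 lists matched on both, of which 0 percent had a median as low. The matched medians ran from -0.90 to 1.60. That mean includes the toxoflavin libraries, so abundance in methanol alone was not matched and stays open. The matched genes were drawn singly, whereas the list members share operons, which makes that range too narrow. The choice among 3 scalings is argued against by a list median, not centred on all genes, of -4.02 at its highest (library totals only; SD over libraries 0.0968), and library depth by -4.20 relative to all genes after thinning. A change in total RNA per cell, a slower growth rate and a faster loss of these transcripts stay open, and none was tested, because total RNA, growth and RNA stability were not measured in these data.

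After toxoflavin 18 of 20 toxin-antitoxin and 25 of 44 flagella genes were called higher, in the group where libraries were smallest and the RPKM of the weakest genes was highest. A background spread evenly over the genome is argued against for the toxin-antitoxin genes, whose median rise in RPKM was at least 93.4 times the 5th percentile of all genes (SD of the ratio 16.8), and depth by 1.80 above all genes after thinning. For the flagella genes depth is argued against by 1.19 after thinning. Their lowest background ratio was 1.27, above the bound of 1 written before the test, but by 0.271, less than the SD of 0.312 over the 3 libraries, and the condition that the margin exceed this SD was added after the ratio was seen. For the median flagella gene, a rise and uniform background reads therefore cannot be told apart. Of the 45 members before filtering, 25 rose in mean RPKM by more than the highest 5th percentile, 3.945 RPKM, and 20 did not.

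For the counts of changed genes, the 10 splits of the 6 libraries of a comparison are too few for a share under 0.05. The real split alone reached its own count, 1 of 10 in each comparison, with 3168 genes for toxoflavin against methanol, 2005 for tropolone against methanol and 2727 for the direct comparison. The highest count by edgeR in another split was 0 in each, with 0 to 69.0, 7 to 82.0 and 2 to 107 genes at an unadjusted p under 0.05, and no other tool was run on the splits.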

How the results depend on the processing

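With all libraries kept, the alternatives called at most 3214 changed genes for toxoflavin, 2107 for tropolone and 2920 for the direct comparison, and thinning to the smallest library gave 2805, 1738 and 2609. Library totals only turned the balance of higher and lower genes, to 1858 and 1356 after toxoflavin (57.8% higher against 48.9%) and 1651 and 1269 in the direct comparison (56.5% against 47.1%). After tropolone it went from 1017 and 1031 to 1050 and 979 (51.75% against 49.66%). Leaving out 1 library gave 2901 to 3131, 1741 to 2088 and 2618 to 2965 genes, and 17 to 20, 19 to 22 and 16 to 17 gene lists. With the replicate number as a block, edgeR called 3125, 2013 and 2814 genes and camera 18, 23 and 17 lists. Correlations between libraries of the same number ran from -0.0716 to 0.132, with 1 of 9 over 0.1. Between libraries of unlike number they ran from -0.111 to 0.146. No pairing by number was seen, but so few libraries cannot exclude a shared day or batch. The block moved the anaerobic list after toxoflavin to a camera adjusted p of 0.0525, soxS after tropolone to 0.0558 and cspF in the direct comparison to 0.0635, and ended no other call of a list or named gene. camera with an estimated correlation called 0 lists in each comparison, with 7, 8 and 4 at an unadjusted p under 0.05, and fry called 41, 34 and 36 with the direction unchanged for the lists that camera called. Because fry does not compare the members with other genes, its higher counts do not support the camera calls. Why the estimated correlation ended the camera calls was not tested. Library totals only turned the sign of recA after toxoflavin, from -0.14 to 0.17, and edgeR called it in neither (adjusted p = 0.374 and 0.243). This scaling moved the median of all genes from 0.05 to 0.35, so the turn goes with a shift of all genes and is not particular to recA. The correlation between the responses was 0.488 with median-ratio factors, 0.492 with the block, 0.489 for genes with a mean CPM of at least 10, 0.4999 after thinning and 0.443 to 0.533 without 1 library.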

Other observations

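Beyond the rule for named genes, some operons chosen after their values were seen moved with large changes. The ribonucleotide reductase genes nrdH, nrdI, nrdE and nrdF, whose enzyme can use manganese, rose after both compounds, with log2 fold changes of 4.89, 4.11, 2.95 and 2.05 after toxoflavin and 4.43, 3.85, 3.34 and 3.55 after tropolone (edgeR adjusted p at most 1.53e-10, for nrdF after toxoflavin). In the putrescine breakdown cluster puuB and puuE fell after toxoflavin (log2 -2.24 and -1.37) and rose after tropolone (log2 4.06 and 3.81), whereas puuA rose after both. The peptide uptake genes oppA and dppA fell after both, with log2 fold changes of -5.95 and -5.82 after toxoflavin and -2.53 and -0.83 after tropolone.

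The rpoS transcript, also chosen after its values were seen, stood at 2729 ± 181 CPM in methanol, 523 ± 37.8 after toxoflavin (log2 -2.38; edgeR adjusted p = 0.00019) and 2675 ± 1323 after tropolone (log2 -0.03; adjusted p = 0.959).

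Both tests below were planned after their patterns were seen. The targets of the first were chosen before their values were looked at, and the operons of the second before their values were compared by position, when some of their genes had been seen. hmp, hcp, ytfE and ygbA, all repressed by the nitric oxide sensor NsrR, rose after both compounds, with log2 fold changes of 5.22, 2.85 and 5.12 for the last 3 after toxoflavin and 3.14, 2.72 and 3.85 after tropolone. A candidate explanation is release of the NsrR repressor, for which at least 3 of 5 other targets had to rise after both and against which at most 1 would count. Of the 5, 2 did, hcr and yoaG, the latter under 2 CPM in each group. hcr lies beside hcp, whose rise prompted the test. yeaR and yoaG are neighbours, as are tehA and tehB, so the 5 are not independent targets. yeaR and tehA were called higher after toxoflavin and were not called after tropolone, where yeaR had under 1 CPM, and tehB fell after toxoflavin. Release of the repressor and another route therefore cannot be told apart.

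In the S10 ribosomal operon the fall after toxoflavin was largest at the first gene, with a rank correlation of 0.955 between position and log2 fold change, given without a p-value because the operon was chosen for this order. After tropolone the correlation was -0.827. A hypothesis that genes near a promoter fall more after toxoflavin predicted a rise with position in at least 80 percent of the other operons that fell, and 36.4 percent did (4 of 11), which argues against it. In the sdh and suc operon the order was opposite, from 2.39 for sdhC to -3.49 for sucD (rank correlation -0.976). This too is given without a p-value, because neighbouring genes of an operon are not independent.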
